A study of Mus musculus with 29 samples.

How the data were processed

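The deposited tables gave RPKM (reads scaled to transcript length and library size) for mouse genes and transcripts, in separate tables for day 3 epidermis, day 3 dermis and the week 1 tissues. Per the submitters' notes, reads were aligned with TopHat2 2.1.0 and quantified in Partek against mm10. The RPKM table headers also name mm10, whereas the header of the deposited week 1 comparison table names mm9. Complementary DNA was made with a NEBnext kit, and libraries were made with a NuGen kit on a Mondrian system and sequenced on Illumina HiSeq instruments. How reads shared between genes were split, whether the libraries kept strand, and whether each library came from a separate animal are not given in the sources used here.

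Per the file headers, the expression values were RPKM, and this is how they were used. The group means in the deposited comparison tables were log2 values; the authors' means were recovered within 0.01 as the mean of log2(RPKM + 0.001) at week 1 and of log2(RPKM + 0.1) elsewhere. The deposited ratios and p values of the authors were read as given and used for Dlx3, for the direction of change and for the number of entries at p < 0.05. The deposited tables also recorded depth, as alignments for the day 3 tables and as reads in the FASTQ files at week 1. Whole read counts were recovered from RPKM and depth for only 22.8%, 17.6% and 14.2% of features (tolerance 0.03), so counts were not used.

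The day 3 epidermis table listed 24543 genes. The week 1 table listed 34138 transcript entries for 24081 genes, 5322 of them with more than 1 entry, and the day 3 dermis table listed 35680 entries for 24453 genes, 5679 of them with more than 1 entry after 832 exact duplicates were dropped. RPKM of transcripts of 1 gene were summed. Dlx3 was taken as ENSMUSG00000001510.8, chromosome 11, 95120119 to 95125296, plus strand, in mm10 (GENCODE M21). Which exons were deleted is not given in the sources used here, so reads from remaining exons count towards Dlx3.

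The columns named a group and no replicate number, so the libraries of a group were lettered a to d, and the letters are names only. The genotype field disagreed with the title for 2 of the 29 samples, both from week 1 epidermis; the table headers went with the titles, and the titles were followed. Per the file headers, the untreated day 3 epidermis libraries were from vehicle-treated skin, the others from skin given a STAT3 inhibitor, and tamoxifen was topical for week 1 epidermis and intraperitoneal for week 1 dermis. The tables came from separate sequencing runs and were normalized separately, so time and tissue were confounded with run, and only libraries of the same table were tested against each other.

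The comparisons, the filter, the thresholds, the gene lists and most alternatives were chosen before the data were examined. Values were analysed as log2(RPKM + 1) with linear models and empirical Bayes moderation with an intensity trend in limma 3.58.1. A gene was tested if it reached 1 RPKM in at least as many libraries as the smaller compared group held. The 15 day 3 epidermis libraries shared a fit, so the WT and icKO comparisons used a spread estimated over all 4 groups; day 3 dermis and each week 1 tissue had a fit of their own, and the tissue by genotype interaction used all 8 week 1 libraries. P values were adjusted by the Benjamini-Hochberg method over the tested genes of a comparison, with 0.05 as the threshold, and the verbs rose and fell are used only for genes past it.

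The 33 curated gene lists were written from general knowledge of skin biology and tested with camera in limma, with a preset correlation between genes of 0.01 and, as an alternative, a correlation estimated from the residuals of each list. Camera tests members against all other tested genes. Counts of members adjusted over the list alone are given for some lists only. All other counts of members are over all tested genes. Genes were named by rule: Dlx3 and 7 fixed genes, the 8 largest rises and 8 largest falls past the threshold whose groups did not overlap, and the 3 lowest adjusted p values of each list that passed camera or had at least 3 members past the threshold. With fewer than 5 genes past the threshold, the 5 smallest p values in each direction were named. Il17a and Il22, both fixed, did not pass the filter in any table.

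The test of whether the icKO effect was smaller with the inhibitor was to use untreated libraries split by replicate number, to choose genes in one part and measure them in the other. The columns carry no such numbers, so all 36 such splits were used. Averaging the closest pair of libraries in each of 3 groups, a term for sex, the removal of WT library b and icKO library c, a covariate for hair shaft transcripts, removal of the day 3 dermis library of lowest depth and a week 1 fit of all libraries for each tissue were added after the data were seen. Sex was read from Xist and Ddx3y, with 1 RPKM as the threshold. In the sex term, untreated icKO library c of day 3 epidermis, with both transcripts, was set midway between the sexes. Only that library and untreated WT library c departed from the sex of their group, so the term rests on them. Other ways of dividing the same libraries into groups of the same sizes were tested to learn how many genes passed by chance, all of them for comparisons of a pair of groups and 100, the real one included, drawn at random for the interaction. Other scaling was quantile normalization or median-ratio scaling of the RPKM.

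Values were simulated from the mean and spread of each gene, with independent noise and no group difference. Changes of 2-fold were then made in 100 genes and of 4-fold in another 100, all above a minimum level. Of 2-fold changes, 88% were recovered in day 3 icKO against WT epidermis, 87% with the inhibitor and 78% for the interaction; the share was 37% in day 3 dermis, 1% in week 1 epidermis, 23% in week 1 dermis and 7% for the tissue interaction. Of 4-fold changes, the shares were 99%, 99%, 97%, 75%, 48%, 68% and 54%. With nothing added, 0 genes were called, and unchanged genes made up 2.2% to 7% of calls. The simulation held no correlation between genes and no libraries that stand apart, so these shares need not hold for the real libraries. Other groupings of the real libraries called up to 3155 genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 and R 4.3.3 were used.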

Results

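RNA was sequenced from the skin of mice in which Dlx3, a homeobox transcription factor of differentiating epidermis and hair, was deleted in adults by a tamoxifen-inducible Cre under the keratin 14 promoter (icKO), and from control mice (WT). Day 3 epidermis was represented by 4 WT and 4 icKO libraries without inhibitor, here called untreated, and by 3 WT and 4 icKO libraries from skin given a STAT3 inhibitor (STAT3i). STAT3 is a transcription factor activated by cytokine and growth factor receptors. Day 3 dermis was represented by 3 WT and 3 icKO libraries, and 1 week after tamoxifen each tissue was represented by 2 WT and 2 icKO libraries. The mice were of mixed background. Recorded depth was 48.9 to 70.3 M alignments per library in day 3 epidermis, 10.1 to 37.3 M alignments in day 3 dermis, and 37.3 to 57.3 M reads at week 1.

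The tissues were not pure. Day 3 epidermis libraries held 2185 to 5355 RPKM of the skeletal muscle actin Acta1 and 316 to 4482 RPKM of the collagen gene Col1a1, and the mean log2 level of the skeletal muscle list was 7.45 to 8.99 per library. In week 1 epidermis that mean was 0.58 to 1.28, and Col1a1 was at 1.64 to 25.3 RPKM. Day 3 dermis in turn held 973 to 6612 RPKM of the epidermal keratin Krt10.

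Dlx3 was lower in icKO than in WT libraries in 4 of the 5 sets of libraries in which the genotypes can be compared. In untreated day 3 epidermis the WT libraries a to d had 3.04, 0.95, 7.13 and 7.21 RPKM (4.58 ± 3.11, SD, n = 4) and the icKO libraries 1.5, 1.58, 2.22 and 1.29 RPKM (1.64 ± 0.40, SD, n = 4). WT library b thus lay below every icKO library. The log2 change was -0.87 ± 0.34 (SE) and did not pass the threshold (adjusted p = 0.108). With STAT3i, WT libraries had 6.77, 6.07 and 6.31 RPKM and icKO libraries 1.01, 1.71, 1.66 and 1.19 RPKM, and Dlx3 fell by 1.64 ± 0.37 (log2, SE, adjusted p = 0.00471). At week 1, Dlx3 was at 3.17 and 5.79 RPKM in WT and 1.46 and 1.82 RPKM in icKO epidermis (adjusted p = 0.03, and 0.258 after quantile normalization). In dermis it was at 2.81 and 5.21 RPKM in WT and 0.14 and 0.167 RPKM in icKO (adjusted p = 0.00209). Week 1 icKO dermis also held less Krt14, at 329 and 254 RPKM against 784 and 1164 RPKM in WT. The mean log2 level of the hair shaft list was 0.7 and 0.9 against 3.11 and 3.45. A loss of Dlx3 within cells thus cannot be told apart there from a smaller share of hair and keratinocyte RNA. Day 3 dermis went against the labels: libraries labelled WT had 3.58, 20.5 and 2.19 RPKM and libraries labelled icKO 64.3, 65.9 and 1.75 RPKM (log2 change 1.75 ± 1.42, SE, adjusted p = 0.513). The authors' deposited ratios of icKO to WT for Dlx3 were 0.472 (p = 0.0607) in untreated day 3 epidermis, and 0.226 (p = 0.00277) with STAT3i, both p values being those of the deposited table and not permutation values. The ratios were 3.56 in day 3 dermis, 0.381 in week 1 epidermis and 0.04 in week 1 dermis.

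**Figure D1:**
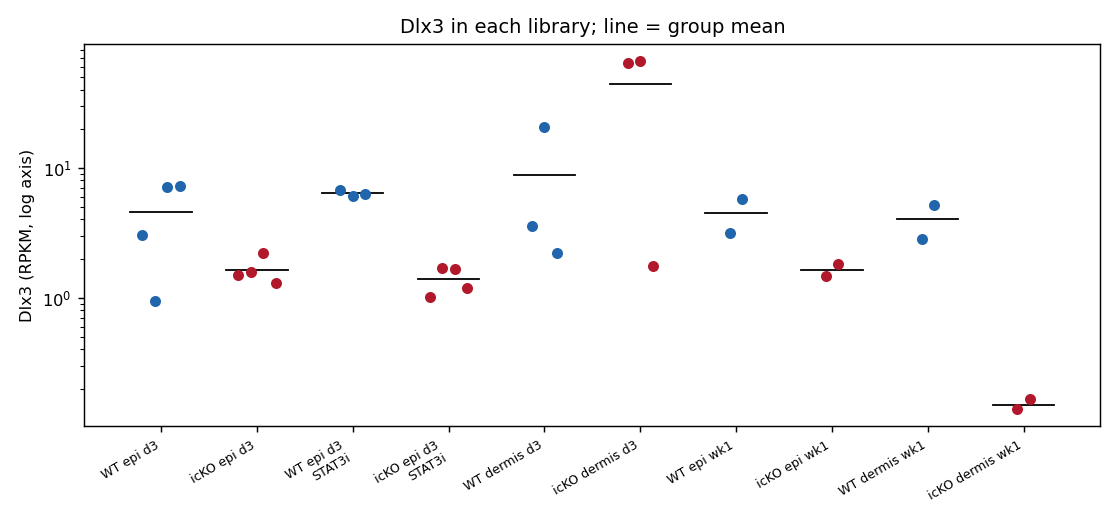
Dlx3 level (RPKM, log axis) in each library, by tissue, time, genotype and STAT3i. Points are libraries (blue WT, red icKO) and lines are group means, 4.58 and 1.64 RPKM in untreated day 3 WT and icKO epidermis.

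Keratins, cornified envelope genes and protease inhibitors made up the largest rises in untreated day 3 icKO epidermis. Krt6b, a keratin of wounded and overgrowing epidermis, was at 427 ± 150.0 RPKM in icKO and 23.6 ± 43.8 RPKM in WT (SD, n = 4 each), a log2 change of 6.02 ± 0.93 (SE, adjusted p = 0.0033). Its partner Krt16 was at 592 ± 204 against 41.7 ± 68.2 RPKM (SD, n = 4 each, log2 change 5.08 ± 0.77, SE, adjusted p = 0.003). The envelope precursor gene Sprr1b rose by 5.43 ± 0.91 (log2, SE, adjusted p = 0.00444). The WT spread came from library b, with 89.2 RPKM of Krt6b against 0.817 to 2.92 RPKM in the other WT libraries. Among genes that fell, Lor, which encodes the main envelope protein loricrin, went from 716 ± 326 to 243 ± 32.4 RPKM (SD, n = 4 each, adjusted p = 0.00703). Wfdc21, Adh6a, Dapl1 and Scgb1a1 fell by 1.42 to 2.03 (log2). Rises of Stfa1, Stfa3 and the Sprr2a genes, of 4.97 to 5.95 (log2), belong to groups of near-identical copies and are uncertain as to the copy.

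Cytokine genes rose with them. Il1b was at 3.73 ± 0.83 RPKM in icKO and 0.834 ± 0.448 RPKM in WT (SD, n = 4 each, adjusted p = 0.00125), and Il1f6, which encodes IL-36 alpha, rose by 1.46 ± 0.23 (log2, SE, adjusted p = 0.0033). Stat3 itself was at 47.3 ± 3.13 against 35.1 ± 4.51 RPKM (SD, n = 4 each), a log2 change of 0.42 ± 0.10 (SE, adjusted p = 0.0163). Its target Socs3 (0.02 ± 0.19, log2, SE, adjusted p = 0.946) and the Langerhans cell gene Cd207 (adjusted p = 0.814) did not pass. Il17a and Il22 stayed below the filter in every table.

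By gene list, 22 of 33 tested late cornified envelope genes rose and 3 fell, with a median log2 change of 2.06, Rptn, Lce3d and Sprr2e among the rises (camera adjusted p = 1.33e-08, adjusted p = 0.366 with an estimated correlation). Of 10 stress keratins 7 rose (median 1.62, camera adjusted p = 0.000232, adjusted p = 0.366 with an estimated correlation). Among 21 antimicrobial genes 12 rose and 1 fell, Defb3 and Defb14 among the former (median 0.99, camera adjusted p = 1.7e-06, adjusted p = 0.363 with an estimated correlation). The IL-1 and IL-36 family had 10 rises and 1 fall among 16 members, Il1a included (median 0.56, camera adjusted p = 0.000425, adjusted p = 0.354 with an estimated correlation). Chemokines gave 7 rises among 24, or 11 adjusted over the list alone, with Ccl17, Ccl20 and Ccl22 among them (median 0.82, camera adjusted p = 0.00424, adjusted p = 0.366 with an estimated correlation). Cell cycle genes rose at 16 of 27, such as Top2a and Ccnb2 (median 0.63, camera adjusted p = 1.33e-08, adjusted p = 0.366 with an estimated correlation). Of 31 STAT3-linked genes 10 rose, Socs1, Il4ra and Bcl3 among them, and 1 fell (median 0.20, camera adjusted p = 0.00714, adjusted p = 0.366 with an estimated correlation). The IL-17 list (3 rose, 1 fell of 8, camera adjusted p = 0.261), interferon-stimulated genes (camera adjusted p = 0.0726) and EGFR ligands (4 rose of 8, camera adjusted p = 0.244) did not pass as lists.

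Layer and cell-type lists moved less evenly. Of 29 spinous and granular genes 10 rose and 2 fell (median 0.14, camera adjusted p = 0.148). Lipid barrier genes had 9 rises and 1 fall among 19 (median 0.28, camera adjusted p = 0.00618, adjusted p = 0.416 with an estimated correlation). Basal layer genes had 0 rises and 2 falls, Krt15 and Dst, among 15 (median -0.16, camera adjusted p = 0.0358, adjusted p = 0.52 with an estimated correlation). Sebaceous gland genes rose at 7 of 17, including Elovl3 and Fabp5 (median 0.50, camera adjusted p = 0.0034, adjusted p = 0.366 with an estimated correlation). Mast cell genes rose at 7 of 8 and fell at 1, the rises including Tpsb2 and Cma1 (median 0.65, camera adjusted p = 0.00214, adjusted p = 0.366 with an estimated correlation). Langerhans and antigen presentation genes gave 3 rises among 15, Itgax and Ccr7 included (median 0.48, camera adjusted p = 0.00439, adjusted p = 0.444 with an estimated correlation). The macrophage list had a median of 0.87 with 1 rise, Ccr2, and 1 fall, Arg1, among 18. Its mean log2 level was 5.31 and 5.47 in WT libraries a and b against 3.6 and 3.76 in WT c and d. Adipocyte genes (median -0.44, 0 members past the threshold, camera adjusted p = 0.0016) and Schwann cell genes (median -0.29, 2 falls among 9, camera adjusted p = 0.00117) were lower, each at adjusted p = 0.366 with an estimated correlation. Sex was unbalanced: 3 WT libraries carried Ddx3y and 1 carried Xist, while 3 icKO libraries carried Xist and library c carried both.

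In all, limma called 1679 of 13095 genes, 1194 higher and 485 lower, 628 of them by at least 1.5-fold. Of the calls 71.1% were higher, against 44.7% after quantile normalization. With the closest pair of libraries of each of 3 groups averaged, a choice made after the data were seen, 41 genes were called, among them Il1b, Rptn, Lce3d, Lce3e, Sprr2e, Gjb6, Defb14, Defb3 and Elovl3 but not Krt6b, Krt16, Il1f6, Stat3 or Lor. A sex term gave 1024 calls, 468 higher and 556 lower, 555 of them among the 1679, and a fit of these groups alone gave 106. Single libraries left out gave 455 (icKO b), 470 (icKO a), 642 (WT d), 794 (icKO d) and 3010 (WT b) calls.

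**Figure D2:**
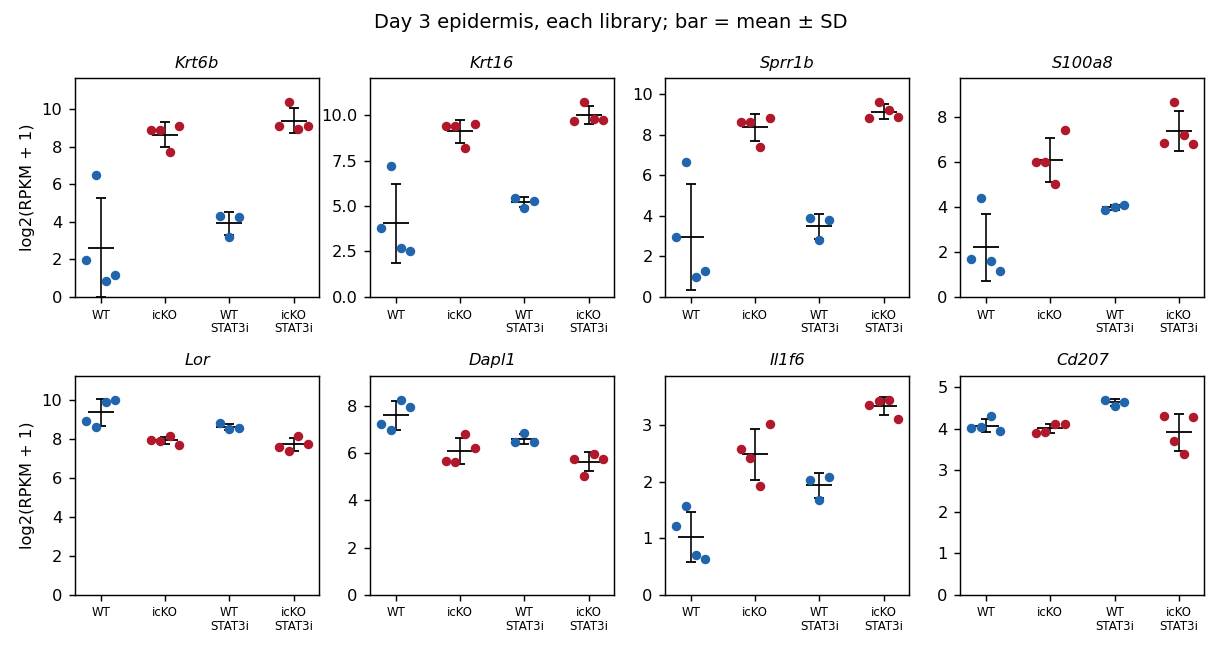
Level (log2(RPKM + 1)) of 8 genes in day 3 epidermis of WT and icKO mice, untreated and with STAT3i. Points are libraries (blue WT, red icKO) and bars are means with SD; Krt6b averaged 427 RPKM in untreated icKO and 23.6 RPKM in untreated WT libraries.

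With STAT3i, keratins and envelope genes were again among the largest rises in icKO epidermis. Sprr1b was at 578 ± 156 RPKM in icKO (SD, n = 4) and 10.9 ± 4.35 RPKM in WT (SD, n = 3), a log2 change of 5.64 ± 0.98 (SE, adjusted p = 0.00101). Krt1, a keratin of the layers above the basal layer, was at 3815 ± 699 against 777 ± 57.8 RPKM (SD, n = 4 and 3, adjusted p = 7.25e-05). The cross-linking enzyme gene Tgm1 was at 49.0 ± 4.91 against 18.4 ± 0.805 RPKM (SD, n = 4 and 3, adjusted p = 8.32e-06). Il1f6 rose by 1.41 ± 0.24 (log2, SE, adjusted p = 0.000994), Stat3 by 0.52 ± 0.11 (log2, SE, adjusted p = 0.0027) and Socs3 by 0.61 ± 0.20 (log2, SE, adjusted p = 0.0327). Cd207 fell, from 23.8 ± 1.32 to 14.6 ± 4.64 RPKM (SD, n = 3 and 4, adjusted p = 0.00843). So did Lce1m, from 285 ± 13.5 to 37.5 ± 3.08 RPKM (SD, n = 3 and 4, adjusted p = 0.00165). Defb7 was listed at 0 in icKO libraries. The falls of Eif2s3y and Ddx3y and the rise of Xist, of 3.43 to 4.80 (log2), followed sex, since all WT STAT3i libraries carried Ddx3y and all icKO STAT3i libraries Xist.

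Of 30 spinous and granular genes 20 rose and 4 fell, with Grhl3, Krt1 and Tgm1 among the rises (median 0.78, camera adjusted p = 1.62e-06, adjusted p = 0.415 with an estimated correlation). Lipid barrier genes rose at 13 of 19 with 0 falls, Alox12b, Sdr9c7 and Pnpla1 among them (median 0.82, camera adjusted p = 7.39e-08, adjusted p = 0.415 with an estimated correlation). Cell cycle genes rose at 25 of 29, or all 29 adjusted over the list alone, such as Rrm2 and Ccnb1 (median 0.82, camera adjusted p = 5.45e-10, adjusted p = 0.415 with an estimated correlation). Interferon-stimulated genes rose at 18 of 28, or 23 adjusted over the list alone (median 0.96, camera adjusted p = 1.19e-05, adjusted p = 0.503 with an estimated correlation). The mean log2 level of this list was 3.59 to 3.76 in icKO STAT3i libraries a, c and d, but 2.54 in b, near the 2.26 to 2.44 of the WT STAT3i libraries. Isg15 went from 3.71 ± 0.468 to 34.4 ± 22.8 RPKM (SD, n = 3 and 4). Late envelope genes gave 20 rises and 5 falls among 34 (median 1.79), stress keratins 7 rises among 10 (median 1.88) and antimicrobial genes 13 rises and 1 fall among 21 (median 1.22). They were at camera adjusted p = 0.000241, 0.000305 and 0.000239, and at adjusted p = 0.503, 0.415 and 0.415 with an estimated correlation. Of 32 STAT3-linked genes 16 rose, Fosl1 and Bcl3 included, and 6 fell, Il6ra included (median 0.41, camera adjusted p = 0.105). Langerhans and antigen presentation genes had 1 rise and 5 falls among 15, H2-Aa and Cd74 falling (median -0.58, camera adjusted p = 0.0314, adjusted p = 0.558 with an estimated correlation). Cd74 was at 1162 ± 218 against 2509 ± 280.0 RPKM (SD, n = 4 and 3). Fibroblast genes had 1 rise and 5 falls among 17, Dcn included (median -0.70, camera adjusted p = 0.0123, adjusted p = 0.558 with an estimated correlation). With a sex term the direction of the fibroblast list turned (adjusted p = 0.000199 in limma). The mean log2 level of this list was 6.67 to 7.20 in icKO STAT3i and 7.56 to 7.81 in WT STAT3i libraries. Col1a1 was at 657 to 983 against 2874 to 3695 RPKM, and Krt14 at 2082 to 4152 against 1058 to 1221 RPKM. A larger share of epidermis in icKO STAT3i tissue was not tested here. It cannot be told apart from the rises of the spinous and lipid barrier lists. Sebaceous gland genes rose at 9 of 17 with 1 fall (median 0.65, camera adjusted p = 0.00126, adjusted p = 0.415 with an estimated correlation).

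Of 13241 genes, 4496 passed in limma, 2632 higher and 1864 lower, 1340 of them by at least 1.5-fold. Averaging the closest pairs, a choice made after the data were seen, gave 1800 calls, all among the 4496, and leaving out WT STAT3i library c gave 2962. A sex term gave 450 calls, 194 higher and 256 lower, 377 of them among the 4496, and 174 of the 4496 took the opposite sign without passing. As genotype and sex went together here, that term drew on the untreated libraries alone and turned the direction of Mpo, C7 and Cyp2g1 besides the sex-linked genes. Across 2 comparisons that share a fit but no libraries, 771 of the 1190 genes that rose without STAT3i also rose with it (235.6 expected by chance), and 235 of the 479 that fell also fell (67.1 expected). The expected numbers assume independent calls. Both comparisons used the same spread estimate for each gene and were unbalanced for sex in the same direction, which can raise the overlap without a shared icKO effect. The correlation of log2 changes across genes, which are not independent replicates, was 0.568.

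In icKO epidermis, STAT3i went with higher Il1f6 and Krt1. Il1f6 went from 4.82 ± 1.80 to 9.17 ± 1.05 RPKM (SD, n = 4 each, adjusted p = 0.0441) and Krt1 from 1857 ± 727 to 3815 ± 699 RPKM (SD, n = 4 each, adjusted p = 0.0227). Lce3f, a late envelope gene, rose by 2.21 ± 0.27 (log2, SE, adjusted p = 0.00102), and Slurp1 by 1.2 (log2, adjusted p = 0.0301). Paqr7, a progestin receptor gene, fell from 41.0 ± 6.39 to 11.5 ± 5.57 RPKM (SD, n = 4 each, adjusted p = 0.000791), and Zbtb16, Mrgprg, Tchh, Cdkn1c and Fam107a fell by 1.16 to 1.70 (log2). Tchh, a gene of the hair sheath, was at 8.20, 8.70 and 4.25 RPKM in untreated icKO libraries a to c and 1.73 RPKM in d, so its fall rests on a to c. Stat3 did not pass (0.22, log2, adjusted p = 0.186), nor did Dlx3 (-0.14 ± 0.34, log2, SE, adjusted p = 0.834). Changes of Rplp2-ps1, Aldoart1, Oaz1-ps and H2-L concern pseudogenes or copies that vary between strains and are uncertain.

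Spinous and granular genes had 6 rises among 29, Ovol1 and Grhl3 included, and 11 rises and 1 fall adjusted over the list alone (median 0.33, camera adjusted p = 0.000163, adjusted p = 0.504 with an estimated correlation). Lipid barrier genes had 2 rises, or 6 adjusted over the list alone (median 0.24, camera adjusted p = 0.000163, adjusted p = 0.504 with an estimated correlation). NRF2 targets had 4 rises among 16, Nqo1, Osgin1 and G6pdx included (median 0.13, camera adjusted p = 0.0119, adjusted p = 0.504 with an estimated correlation). Interferon-stimulated genes (median 0.50) and cell cycle genes (median 0.29) were higher as lists, both at camera adjusted p = 3.53e-05 with 0 single members past the threshold in limma, and both at adjusted p = 0.625 with an estimated correlation. The interferon level of icKO STAT3i library b (mean log2 2.54) lay below all untreated icKO libraries (2.55 to 3.10). STAT3-linked genes did not move as a list: 1 of 32, Fosl1, rose and 2, Bcl2l1 and Il6ra, fell (median 0.00, camera adjusted p = 0.992). Mast cell genes (median -0.28, 2 falls, Tpsb2 and Mrgprb1, camera adjusted p = 0.0109) and skeletal muscle genes (median -0.47, 1 fall, Pvalb, camera adjusted p = 0.000131) were lower, at adjusted p = 0.585 and 0.625 with an estimated correlation. In icKO epidermis 727 of 13074 genes passed in limma, 368 higher and 359 lower, 142 of them by at least 1.5-fold, and 20 with the closest pairs averaged, Lce3f, Prex2 and Paqr7 among them, a choice made after the data were seen. Leaving out icKO library b, a, c or d gave 86, 109, 122 or 1260 calls. Leaving out icKO STAT3i library a, b or d gave 169, 233 or 125, and leaving out both WT library b and icKO library c gave 193.

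In WT epidermis STAT3i went with higher antigen presentation and macrophage genes. Cd74, the invariant chain of class II molecules, went from 873 ± 403 to 2509 ± 280.0 RPKM (SD, n = 4 and 3, log2 change 1.62 ± 0.26, SE, adjusted p = 0.00359). Csf1r, a receptor gene of macrophages, went from 88.8 ± 61.8 to 220.7 ± 19.1 RPKM (SD, n = 4 and 3, adjusted p = 0.0234). Ccl27a, a chemokine gene of keratinocytes, rose from 20.5 ± 2.30 to 48.0 ± 8.04 RPKM (SD, n = 4 and 3, adjusted p = 0.00206). Cd207 rose by 0.56 ± 0.18 (log2, SE, adjusted p = 0.0454), and Il1f6 and Il1b rose by 0.91 and 0.58 (log2, adjusted p = 0.0234 and 0.0333). Langerhans and antigen presentation genes rose at 13 of 15, Ciita and H2-Aa among them (median 1.04, camera adjusted p = 3.56e-07). Macrophage genes rose at 12 of 18, Itgam included (median 1.52, camera adjusted p = 2.98e-05), and chemokines at 9 of 24, Ccl22 and Ccl21a included (median 0.66, camera adjusted p = 0.000552). These lists had 0 falls, and each was at adjusted p = 0.738 with an estimated correlation. Spinous genes (3 falls of 30, Dsc1 included, median -0.33), basal layer genes (4 falls, Itga3, Itga6 and Col7a1 included, median -0.37), desmosome genes (3 falls, median -0.32) and lipid barrier genes (8 falls and 1 rise, Cers3 and Alox12b falling, median -0.32) were lower. They were at camera adjusted p = 0.00202, 0.0119, 0.0119 and 0.0265, each at adjusted p = 0.738 with an estimated correlation. STAT3-linked genes had 4 rises and 1 fall among 30 (median 0.03, camera adjusted p = 0.583). Klk1b21, Klk1b24 and Klk1b27, with rises of 3.79 to 4.38 (log2), and Cd300ld4 and Cd300ld5, with identical values, are near-identical copies and uncertain.

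In WT epidermis 2480 of 13211 genes passed in limma, 1441 higher and 1039 lower, 806 of them by at least 1.5-fold. Of these 58.1% were higher, against 46.1% after quantile normalization. With the closest pairs averaged, a choice made after the data were seen, 55 genes were called, Ccl27a among them and Cd74, Csf1r and Cd207 not. A fit of these groups alone called 245, and leaving out WT STAT3i library a, c or b called 469, 554 or 1548, WT library d or c 1441 or 1522, and both WT library b and icKO library c 3758. Macrophage genes also differed among the untreated WT libraries, with a and b above c and d.

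The interaction of genotype and STAT3i asked which icKO effects differed with the inhibitor. The icKO effect was larger with STAT3i for the barrier genes Dsc1 (by 1.31, log2, adjusted p = 0.0363), Sdr9c7 (by 1.14, adjusted p = 0.0251) and Alox12b (by 0.79, adjusted p = 0.0215). The same held for Tgm1 (by 0.74, adjusted p = 0.0313) and Lce3f (by 1.96 ± 0.40, log2, SE, adjusted p = 0.0377). It was lower for Cd74 (-1.50, log2), H2-Aa (-1.32), Ciita (-1.06), Mgl2 (-2.12) and Paqr7 (-2.0). The icKO effects on Stat3 (difference 0.09, log2, adjusted p = 0.739), Dlx3 (-0.77 ± 0.51, log2, SE, adjusted p = 0.375) and Il1b (-0.78, log2, adjusted p = 0.0754) did not differ past the threshold. Spinous genes had 5 positive differences among 30, and 13 adjusted over the list alone (median 0.58, camera adjusted p = 4.12e-08). Lipid barrier genes had 5 of 19 and 10 over the list alone (median 0.47, camera adjusted p = 2.4e-06), each at adjusted p = 0.479 with an estimated correlation. Langerhans and antigen presentation genes had 3 negative differences among 15 and 11 over the list alone (median -0.98, camera adjusted p = 3.16e-06, adjusted p = 0.479 with an estimated correlation). Hair shaft genes, whose mean log2 level was 1.62, 1.62, 1.24 and 0.45 in untreated icKO libraries a to d and 0.37 to 0.78 in all other day 3 epidermis libraries, had 0 of 16 and 10 negative ones over the list alone (median -0.98, camera adjusted p = 0.000303, adjusted p = 0.558 with an estimated correlation). Fibroblast genes (median -0.88, camera adjusted p = 4.79e-05) and macrophage genes (median -1.52, camera adjusted p = 0.000213) differed negatively as lists, at adjusted p = 0.558 and 0.649 with an estimated correlation, so markers of other tissue moved along with the barrier lists. The mean log2 level of fibroblast genes was 6.05 to 7.77 in WT, 7.56 to 7.81 in WT STAT3i, 7.18 to 7.73 in icKO and 6.67 to 7.20 in icKO STAT3i libraries. STAT3-linked genes did not pass (median -0.06, camera adjusted p = 0.801).

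For the interaction, 290 of 13563 genes passed in limma, 99 higher and 191 lower, 200 of them by at least 1.5-fold. After quantile normalization 355 passed, 182 higher and 173 lower, so the excess of negative differences depended on scaling. With the closest pairs averaged 0 passed, and the lowest adjusted p in limma was 0.286. Calls fell to 0 without WT STAT3i library a or c, 12 without icKO a or b, 29 to 54 without any icKO STAT3i library or WT STAT3i b, and 82 without icKO c. They came to 108 and 122 without WT d and c, 116 without a filter and 16 with a sex term, and rose to 532, 1363 and 1700 without icKO d, WT a and WT b. Over genes chosen in one part of the untreated libraries and measured in the other, the median icKO effect in the genes' own direction was 0.62 untreated and 0.65 with STAT3i (log2). The median difference over 36 splits was -0.02, from -0.54 to 0.36, with 18 of 36 splits showing a smaller effect with STAT3i. A permutation of labels gave p = 0.938 over 64 labelings, but each permuted value came from a single split (-0.64 to 0.58). That p value does not belong to a median over 36 splits and decides nothing.

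Day 3 dermis libraries differed more by hair than by label. Krt71, a keratin of the inner root sheath of growing hair, was at 2.58, 1302 and 0.943 RPKM in libraries labelled WT and 4201, 4682 and 1.01 RPKM in libraries labelled icKO. The mean log2 level of the hair shaft list was 0.91, 7.09 and 0.59 in libraries labelled WT a to c and 9.05, 9.11 and 0.64 in libraries labelled icKO a to c. Dlx3 was above 20 RPKM in the libraries with high hair levels and at 1.75 to 3.58 RPKM in the others. The skeletal muscle list stood at 7.94, 9.07 and 8.29 in libraries labelled WT and 6.16, 6.96 and 7.56 in libraries labelled icKO. No gene passed in limma: 0 of 13017, with 1643 at unadjusted p < 0.05 and a lowest adjusted p of 0.315. That was Stfa1, at 108 ± 27.7 RPKM in libraries labelled WT and 1.28 ± 1.47 RPKM in libraries labelled icKO (SD, n = 3 each). Siva1, at 20.04 ± 0.742 and 40.1 ± 4.43 RPKM (SD, n = 3 each, adjusted p = 0.362), had the smallest p value among genes higher in libraries labelled icKO.

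**Figure D3:**
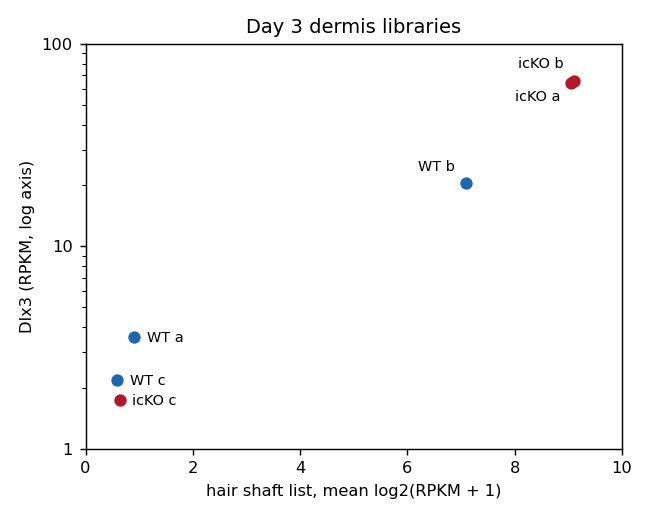
Dlx3 level (RPKM, log axis) against the mean log2(RPKM + 1) of the hair shaft list in the day 3 dermis. Points are libraries, 3 labelled WT (blue) and 3 labelled icKO (red), with Dlx3 from 1.75 to 65.9 RPKM.

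As lists, with 0 single members past the threshold over all genes, hair shaft genes were higher in libraries labelled icKO (median 3.70 over 32 genes, camera adjusted p = 8.86e-05), as were melanocyte genes (2.28, 0.003) and cell cycle genes (0.40, camera adjusted p = 1.34e-05). Skeletal muscle genes (median -1.60, with 14 of 18 falling when adjusted over the list alone, camera adjusted p = 8.96e-10), fibroblast genes (-0.75, camera adjusted p = 8.9e-05), endothelial genes (-0.60, 0.000296), macrophage genes (-1.26, 0.00322), chemokines (-0.96, 0.00437) and STAT3-linked genes (-0.56, 0.0014) were lower. Each of these lists was at adjusted p = 0.634 with an estimated correlation. The count of genes was 3009 without icKO library c and 1 with the hair shaft level as a covariate, and otherwise 0.

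A week after tamoxifen, S100a8 and S100a9, which encode the subunits of calprotectin, headed the rises in icKO epidermis. The median log2 change of all tested genes was -0.50, and changes here are given relative to it, while adjusted p values belong to the values as deposited. S100a9 was at 8462 ± 2510 RPKM in icKO and 22.2 ± 12.4 RPKM in WT (SD, n = 2 each), a relative log2 change of 9.09 ± 0.43 (SE, adjusted p = 0.00132). Sprr1b was at 2484 ± 335 against 11.98 ± 2.02 RPKM (SD, n = 2 each, relative change 8.08 ± 0.19, log2, SE, adjusted p = 0.00087). Il1f6 went from 0.736 ± 0.384 to 22.3 ± 3.21 RPKM (SD, n = 2 each, adjusted p = 0.00152). Krt77, a keratin of suprabasal layers, fell from 3273 ± 413 to 29.03 ± 11.8 RPKM (SD, n = 2 each, adjusted p = 0.00111). Lor fell from 748 ± 123 to 22.2 ± 4.25 RPKM (SD, n = 2 each, adjusted p = 0.00108) and Flg2 by 5.56 (relative log2, adjusted p = 0.00087). Cd207 fell from 43.8 ± 6.37 to 1.34 ± 1.33 RPKM (SD, n = 2 each, adjusted p = 0.00275), and the Skint9 and Skint10 genes fell by 4.88 and 5.03 (relative log2). Stat3, at 28.03 ± 0.744 and 33.5 ± 5.37 RPKM (SD, n = 2 each, adjusted p = 0.292), and Il1b (relative change 1.77, log2, adjusted p = 0.0746) did not pass.

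Late envelope genes rose at 28 of 34 and fell at 4 (relative median 4.76, camera adjusted p = 4.19e-18, adjusted p = 0.495 with an estimated correlation). Antimicrobial genes rose at 22 of 26 and fell at 1 (5.85, camera adjusted p = 9.46e-18, adjusted p = 0.318 with an estimated correlation), Defb3 and Defb14 among the rises. Stress keratins (6 rose, 2 fell of 10, 2.90, camera adjusted p = 0.000207), chemokines (15 rose, Ccl4 and Ccl5 included, and 4 fell, Ccl27a included, 3.06, camera adjusted p = 2.17e-06) and IL-1 and IL-36 family genes (8 rose, 5 fell of 15, 1.67, camera adjusted p = 0.00527) were higher, each at adjusted p = 0.495 with an estimated correlation. So were NRF2 targets (6 rose, 2 fell of 16, 0.96, camera adjusted p = 0.000518) and cell cycle genes (16 rose, 0 fell of 28, 1.35, camera adjusted p = 1.35e-11), at the same adjusted p = 0.495 with an estimated correlation. Interferon-stimulated genes (7 rose, 0 fell of 16, 1.75, camera adjusted p = 4.34e-05), macrophage genes (11 rose, 0 fell of 16, C1qb included, 3.04, camera adjusted p = 3.35e-07) and neutrophil genes (5 rose, 1 fell of 8, Retnlg and Cxcr2 rising, 3.01, camera adjusted p = 0.00138) were higher too, each at adjusted p = 0.592 with an estimated correlation. Immediate early genes (0 rose, 19 fell of 21, Fosb, Egr1 and Nr4a1 included, -1.06, camera adjusted p = 0.000875) and Langerhans and antigen presentation genes (0 rose, 12 fell of 14, -1.41, camera adjusted p = 0.00392) were lower, each at adjusted p = 0.592 with an estimated correlation. After quantile normalization the members past the threshold were 28 higher and 3 lower for late envelope, 21 and 1 for antimicrobial, 6 and 2 for stress keratin, 15 and 2 for chemokine, 9 and 4 for IL-1 and IL-36, 9 and 2 for NRF2 and 24 and 0 for cell cycle genes. They were 8 and 0 for interferon, 12 and 0 for macrophage, 6 and 1 for neutrophil, 0 and 17 for immediate early and 0 and 10 for Langerhans and antigen presentation genes. Spinous genes (3 rose, 15 fell of 30, relative median -0.27, camera adjusted p = 0.255), basal layer genes (1 rose, 9 fell of 16, Krt15, Dst and Col7a1 falling, camera adjusted p = 0.534) and T cell genes (0 rose, 11 fell of 14, camera adjusted p = 0.0719) did not pass as lists. STAT3-linked genes were divided, 12 rising and 13 falling among 35 (camera adjusted p = 0.0719), with Il24 up and Il20rb and Il6ra down. The median of this list changed sign with scaling, from -0.24 to 0.02 after quantile normalization.

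The libraries of the icKO epidermis were not alike, with Krt10 at 787 and 77.4 RPKM against 5781 and 5196 RPKM in WT, and a mean log2 level of macrophage genes of 2.70 and 4.54 against 1.51 and 1.45. A total of 6524 of 11796 genes passed in limma, 1377 higher and 5147 lower, 6132 by at least 1.5-fold. After quantile normalization, which moved the median by 0.446, 4973 passed, 2357 higher and 2616 lower. Leaving out WT library a or b, with the lone library taken to vary like the other group, gave 407 or 1032 calls, Il1f6, S100a9, Sprr1b, Krt77 and Lor kept in both. Genes called in epidermis at both times numbered 743: 375 rose in both (112.9 expected by chance) and 368 fell in both (188.0 expected). Another 120 rose on day 3 and fell at week 1, and 5 did the reverse. These directions are those of the values as deposited, and the numbers depend on scaling. Of the 1024 genes that rose on day 3 and were tested at week 1, 64.1% were higher there as deposited. Relative to the week 1 all-gene median the share was 82.7%. The correlation across genes, which are not independent replicates, was 0.596.

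Hair and keratinocyte genes fell in week 1 icKO dermis. Krt71 went from 83.8 ± 23.8 to 1.54 ± 0.463 RPKM (SD, n = 2 each), a log2 change of -4.67 ± 0.23 (SE) relative to the all-gene median of -0.38 (adjusted p = 0.000696). Krt27, Krt73, Krt25, Krt35, S100a3 and Tchh, genes of the hair sheath and shaft, fell by 3.10 to 4.26 on the same scale. Among rises, Il11, a cytokine gene of the IL-6 family, went from 12.8 ± 10.4 to 89.3 ± 21.7 RPKM (SD, n = 2 each, adjusted p = 0.00531). Tslp, a cytokine gene of damaged epithelium, went from 7.82 ± 2.42 to 35.0 ± 8.69 RPKM (SD, n = 2 each, adjusted p = 0.00219). Stat3 fell from 34.5 ± 3.10 to 15.05 ± 0.487 RPKM (SD, n = 2 each, relative change -0.77 ± 0.14, log2, SE, adjusted p = 0.0022), and Socs3 by 1.35 (relative log2, adjusted p = 0.00196). Il1b fell (relative change -0.73, log2, adjusted p = 0.0341), a call not kept after quantile normalization (adjusted p = 0.136), and Cd207 did not pass (adjusted p = 0.15).

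All 31 tested hair shaft genes fell (relative median -2.20, camera adjusted p = 7.42e-11), as did 25 of 26 spinous genes (-1.17, camera adjusted p = 3.85e-05) and all 15 basal layer genes (-1.35, camera adjusted p = 0.000325), each at adjusted p = 0.63 with an estimated correlation. So did 8 of 9 stress keratins (-1.51, camera adjusted p = 0.00156), 24 of 32 STAT3-linked genes (-0.57, camera adjusted p = 0.000471) and all 11 endothelial genes (-0.84, camera adjusted p = 0.000614), each at adjusted p = 0.63 with an estimated correlation and with 0 rises in all 6 lists. After quantile normalization 26, 21, 13, 8, 17 and 9 members of these lists fell. Macrophage genes (9 rose, 2 fell of 18, Cd68 and Ms4a7 rising, 1.15, camera adjusted p = 2.57e-08) and neutrophil genes (3 rose of 4, Csf3r and Cxcr2 included, 1.53, camera adjusted p = 0.000632) were higher. Skeletal muscle genes were higher as a list with 0 of 12 members past the threshold (median 0.87 as deposited, camera adjusted p = 0.000471). These lists too were at adjusted p = 0.63 with an estimated correlation. The medians of the late envelope, antimicrobial, IL-1 and IL-36, interferon, NRF2, T cell and mast cell lists changed sign with scaling. Of the WT libraries 1 carried Xist and 1 Ddx3y, and both icKO libraries carried Ddx3y.

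Of 12744 genes in week 1 dermis, 6282 passed in limma, 1072 higher and 5210 lower, 5027 by at least 1.5-fold, and 4412 after quantile normalization, 2190 higher and 2222 lower. Leaving out icKO library b gave 3004 calls, with the lone library taken to vary like the other group, and Dlx3, Stat3, Krt71 and Tslp kept their calls under every alternative.

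**Figure D4:**
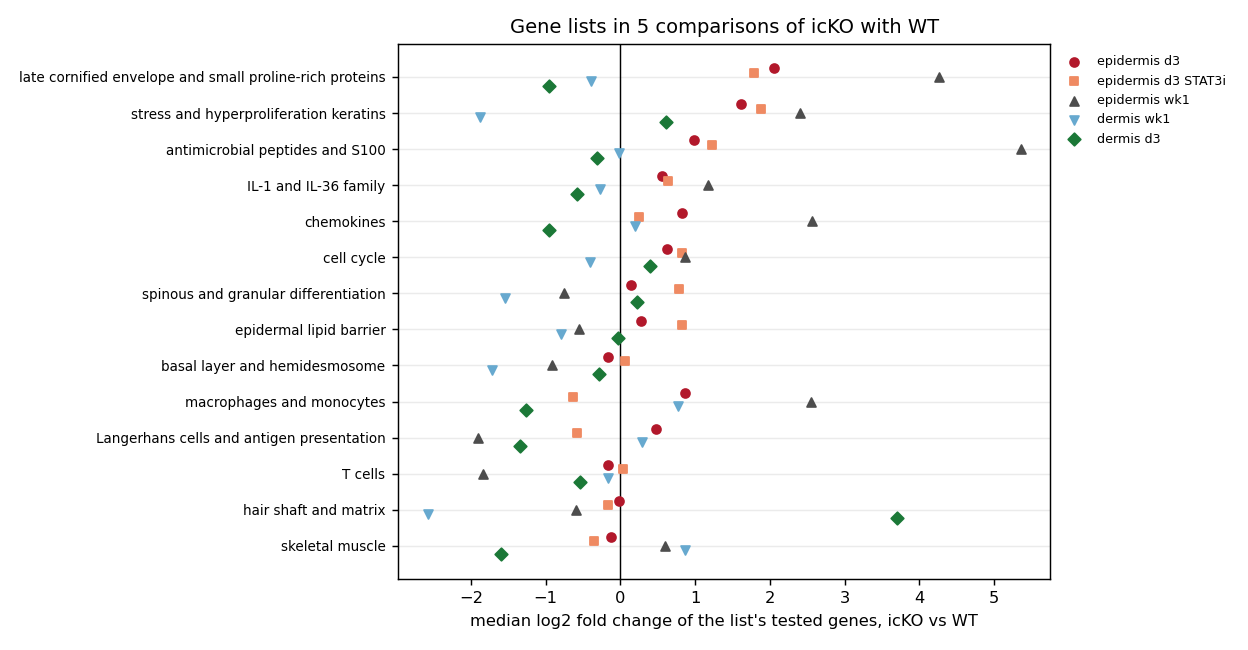
Median log2 change, icKO against WT, of the tested genes of 14 lists. Each symbol is a list in a comparison: epidermis day 3 untreated or with STAT3i, epidermis week 1, dermis week 1 and dermis day 3, from -2.58 (hair shaft, dermis week 1) to 5.36 (antimicrobial, epidermis week 1).

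The effect of icKO at week 1 differed by tissue, and tissue went together with the route of tamoxifen. The largest differences, icKO against WT in epidermis minus the same in dermis, were those of S100a8 (10.20, log2, adjusted p = 3.72e-05), Krt16 (9.48), S100a9 (8.76) and Krt6b (8.59). Stat3 differed by 0.90 ± 0.22 (log2, SE, adjusted p = 0.0196), Il1f6 by 3.72 (adjusted p = 0.000322) and Cd207 by -4.70 ± 0.51 (log2, SE, adjusted p = 0.00138). The difference for Dlx3 was 1.06 ± 0.41 (log2, SE, adjusted p = 0.0834). Antimicrobial genes differed at 21 of 26 (median 5.43, camera adjusted p = 2.38e-12), the only list past the threshold with an estimated correlation as well (adjusted p = 0.0385). Late envelope genes (26 positive, 2 negative of 34, median 4.53, camera adjusted p = 1.35e-13) and endothelial genes (11 positive, 1.62, camera adjusted p = 2.65e-08) were at adjusted p = 0.231 with an estimated correlation. Hair shaft genes (21 positive, 2.43, camera adjusted p = 2.39e-09) were at adjusted p = 0.468 with an estimated correlation. Cell cycle genes (17 positive of 28, 1.09, camera adjusted p = 1.27e-08), Langerhans and antigen presentation genes (9 negative, -1.99, camera adjusted p = 0.000291) and STAT3-linked genes (14 positive, 5 negative of 36, 0.91, camera adjusted p = 0.00704) were at adjusted p = 0.36 with an estimated correlation. For the tissue difference 4403 of 13539 genes passed in limma, 2073 positive and 2330 negative, 4344 by at least 1.5-fold. There were 1899 and 2267 calls without WT epidermis library a or b and 2278 and 2638 without icKO dermis library a or b.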

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

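The tests of other groupings, of repeat libraries and of hair growth were fixed before their results were seen, and the remaining tests in this part were chosen after.

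In day 3 epidermis, 9 of 60 values tested in groups of 4 libraries stood apart from the rest of their group by Dixon's test. For independent values chance gives about 1 in 20. The icKO and icKO STAT3i groups each held a pair of very close libraries, and measures such as Xist and Ddx3y go together. The number that stood apart thus cannot be set against that rate. WT library c had 18.7 RPKM of Xist (others 0.025 to 0.035) and 0.01 RPKM of Ddx3y (others 10.7 to 11.3), so it came from a female among males. Library icKO c had 7.2 RPKM of Xist (others 17.6 to 18), 5.88 RPKM of Ddx3y (others 0 to 0.021) and 3160 RPKM of Col1a1 (others 999 to 1280). With STAT3i, icKO library c had 4610 RPKM of Krt10 (others 3680 to 3760) and 657 RPKM of Col1a1 (others 936 to 983). Library icKO STAT3i b had 4150 RPKM of Krt14 (others 2080 to 2350) and a mean log2 level of interferon-stimulated genes of 2.54 (others 3.59 to 3.76, WT STAT3i libraries 2.26 to 2.44).

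The icKO effect differed with STAT3i for 290 genes, by a test of the difference itself. It was more positive with STAT3i for Lce3f (1.96), Plac8 (1.46), Dsc1 (1.31), Ces2g (1.2), Serpinb2 (1.19), Wfdc5 (1.17), Defb14 (1.16) and Sdr9c7 (1.14) and more negative for Pyy (-5.45), Myl2 (-3.58), Myh7 (-2.68), Tnnc1 (-2.65), Mgl2 (-2.12), Cd209e (-2.1), Stra6 (-2.05) and Paqr7 (-2) (log2 differences). The count of 290 fell to 0 without WT STAT3i library a or c, and with the closest pairs averaged. It was 12 without icKO library a or b and 16 with a sex term. Myl2, Myh7 and Tnnc1 are muscle genes, and the muscle RNA in these libraries (Acta1 2185 to 5355 RPKM) was not accounted for. The icKO effect at week 1 differed between epidermis and dermis for 4403 genes by the same kind of test. It was more positive in epidermis for S100a8 (10.2), Krt16 (9.48), S100a9 (8.76), Krt6b (8.59), Stfa2 (7.92), Sprr1b (7.63), Sprr2d (7.49), Saa3 (7.41), Il1f6 (3.72), Il1b (2.39) and Stat3 (0.9). It was more negative for Defb8 (-8.24), Gng13 (-5.98), Skint9 (-4.96), Skint3 (-4.88), Flg2 (-4.72), Cd207 (-4.7), H2-Eb1 (-4.63) and Mettl7a1 (-4.3).

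Some named genes moved in opposite directions in every library of comparisons from separate tables, and these differences were not tested. Of 33 genes looked at, Stat3 changed by 0.42 in icKO epidermis on day 3 and by -0.24 at week 1 (log2, as deposited), but relative to the all-gene median the week 1 value was 0.25, in the day 3 direction, and it did not pass (adjusted p = 0.292). Of 30 genes looked at in day 3 epidermis and dermis, Stfa1 changed by 5.52 and -5.76 and Scgb1a1 by -1.42 and 1.23. Of 24 genes looked at in dermis on day 3 and at week 1, Gpc4 changed by 0.72 and -1.52, Mpzl3 by 0.79 and -1.29, Stfa1 by -5.76 and 1.17, and Klhl41 by -1.12 and 2.47. Stfa1 belongs to a group of near-identical copies, so its values are uncertain, and the labels of day 3 dermis are doubtful.

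The first pattern weighed was the large number of genes higher in untreated day 3 icKO epidermis, where genotype and sex were unbalanced. In week 1 epidermis all libraries carried Ddx3y. There the 1024 genes of this kind that were tested changed by a median of 0.83 (log2, interval 0.77 to 0.89 over genes) above all genes. This argues against sex as the whole cause. The interval is over genes, which are not independent replicates, and measures no spread between animals. With a sex term on day 3, 468 genes were higher and 556 lower, so a part played by sex stays open. That term rests on WT library c, the only female among the untreated WT libraries, and icKO library c, set midway between the sexes. WT c also had 316 RPKM of Col1a1, against 2269 to 4482 RPKM in the other untreated WT libraries. The term thus cannot part sex from other traits of these libraries. A larger share of epidermis in the icKO tissue stays open: the mean log2 level of basal layer genes minus that of fibroblast genes differed by -0.52 between icKO and WT libraries, against the direction it needs, but icKO libraries (-2.19 to -1.61) lay within the range of WT libraries (-2.28 to 0.01). Repeat libraries counted as separate samples remain open: averaging the 3 closest pairs left 41 genes, against 331 to 1856 for the 50 other choices of pairs, but choosing the closest pairs lowers the count by construction, so this decides nothing. Library pairs icKO a and b, WT STAT3i a and c, and icKO STAT3i a and d differed by 2.14, 1.94 and 1.91 times counting noise, and other pairs of the same group by 2.61 to 9.58 times.

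The second pattern was the presence of growing-hair transcripts in day 3 dermis libraries of both labels. Across 12965 genes outside the hair and melanocyte lists, which are not independent replicates, the difference between WT library b and WT a and c went with that between icKO a, b and icKO c (r = 0.73). The other choices of WT library gave -0.53 and -0.51. As the WT differences cancel out over the choices for each gene, these negative values follow largely by construction and add no support. Follicles in growth phase are therefore a candidate explanation for these levels, Dlx3 included, since the lowest Dlx3 among the libraries with hair was 5.71 times the highest among the others. Exchanged labels could not be told apart from this, because Dlx3 went with hair. No deletion of Dlx3 can be read from the day 3 dermis.

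The last pattern joined both Xist and Ddx3y in icKO library c with the lowest Dlx3 in WT library b of day 3 epidermis, and for the former a mixture of RNA of icKO libraries a or b with RNA of a male fits: over 6 genes particular to a and b, among them Mucl1 and Krt71, library c held a median share of 0.41 (quartiles 0.35 to 0.42), and only 1 of the 6, with a share of 0.33, lies outside the hair lists. Whether the other part came from a deposited library could not be told, as the best mixture differed by a spread of 0.0987, against 0.0516 between a and b and 0.164 for the closest single library. Exchange of the labels of WT b and icKO c gives no library both Xist and Ddx3y, and for Dlx3, which an exchange would part fully (lowest WT 2.22, highest icKO 1.58 RPKM), it stays open. Over 1340 autosomal genes called without both libraries, from 0 (other WT) to 1 (other icKO), WT b stood at a median of 0.65 and icKO c at 0.57, a difference of -0.1 (interval -0.12 to -0.07), and icKO c lay nearer the other icKO libraries for 39.4% of genes. An exchange of unmixed libraries would give a difference near -1, but the limit of -0.5 for counting it was set after the value was seen, and under the first limit, 0, the value counts for an exchange, so the labels were kept and no biological explanation was tested.

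Other groupings of the same libraries showed which counts chance could give. For icKO against WT with STAT3i only the real grouping reached its count (4496 genes, highest other grouping 1059, 1 of 35 groupings). The same held for STAT3i in icKO epidermis (727, highest other 194, 1 of 35), and no smaller share was possible. Chance is thus an unlikely source of these counts only if each library is a separate sample. That is in doubt for WT STAT3i a and c, icKO a and b, and icKO STAT3i a and d. These pairs differed by 1.94, 2.14 and 1.91 times counting noise. With such pairs counted once, the groupings would be too few for a share under 0.05. Between icKO and WT with STAT3i the real grouping was also that by sex. For the interaction (290, highest other 254, 1 of 100 drawn) chance cannot be judged this way. Those groupings shuffled STAT3i labels within each genotype, which also removes any response to STAT3i that both genotypes share. Low counts could thus arise without an interaction. With the closest pairs averaged the counts were 1800, 20 and 0 (lowest adjusted p in limma 0.286 for the last). Chance is not excluded for untreated icKO against WT (1679, highest other 2058, 2 of 35), where the highest was the exchange of WT b and icKO c. Nor is it excluded for STAT3i in WT epidermis (2480, highest other 3155, 2 of 35), where the highest placed WT b with the STAT3i libraries. In day 3 dermis the 10 groupings are too few for a share under 0.05, and the real count was 0 and the highest other 804.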

How the results depend on the processing

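The sex term, the averaging of the closest pairs, the removal of WT library b and icKO library c, the hair covariate, the removal of the day 3 dermis library of lowest depth and the week 1 fits of all libraries were chosen after the results were seen, and the other alternatives before. For named genes, 7389 results kept their side of the threshold, 1357 kept direction only, 31 passed newly and 7 turned. For lists the numbers were 858, 163, 44 and 5. Results past the threshold in neither fit count among the first number whatever their direction. Turns were therefore counted only where a result passed in at least one of the fits. Counts of genes are given in the order untreated icKO against WT, STAT3i icKO against WT, STAT3i in icKO, STAT3i in WT, and interaction, all on day 3. A minimum of 1.5-fold left 628, 1340, 142 and 806 (200 for the interaction), averaged pairs 41, 1800, 20, 55 and 0, and fits of the compared groups alone 106, 6140, 1018 and 245. With a sex term the counts were 1024, 450, 927, 1884 and 16, and without WT b and icKO c they were 3569 for icKO against WT, 193, 3758 and 1535 for the others. No filter left 116 for the interaction. Leave-one-out gave 455 to 3010, 2962 to 4088, 86 to 1260, 469 to 3626 and 0 to 1700 genes, 0 to 3009 in day 3 dermis, 407 to 8841 in week 1 epidermis, 3004 to 6573 in week 1 dermis and 1899 to 5848 for tissue, where a lone library is assumed to vary like the other groups. The hair covariate gave 1 gene in day 3 dermis. Genes called in epidermis at both times numbered 743, or 1607 if an unadjusted p under 0.05 sufficed in one. With an estimated correlation 0 lists passed in every comparison except tissue, where 1 did. The sex term turned Cyp2g1 (-0.46), Eif2s3y (0.66), Ddx3y (0.53), C7 (1.34), Mpo (0.092), Xist (-0.006) and Uty (0.24, log2) with STAT3i, and the sex-linked list (adjusted p = 0.0346 in limma) without. It also turned the macrophage (adjusted p = 0.0313) and fibroblast (adjusted p = 0.000199) lists with STAT3i, and the hair covariate the interferon (adjusted p = 0.00504) and T cell (adjusted p = 0.525) lists in day 3 dermis. The icKO effect with STAT3i minus that without, -0.02 (log2), was 0.03 with 0.1 RPKM added in place of 1. Averaged pairs and leave-one-out hold fewer libraries by construction, and for all other changes the cause was not tested. No paired analysis was possible because the columns carry no replicate numbers, and regrouping by the genotype field could not be run for the same reason. Depth was lowest in day 3 dermis, with 10.1 M alignments in WT library a, and removing that library also gave 0 genes in limma.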

Other observations

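The facts in this part were picked out after the results were seen, and no test was fixed for them beforehand.

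Of 3 tested genes of the Dlx family list, Dlx5 alone passed the threshold. It fell in untreated day 3 icKO epidermis by 0.49 ± 0.11 (log2, SE, n = 4 each, adjusted p = 0.0136), and the list was at camera adjusted p = 0.0166 (adjusted p = 0.363 with an estimated correlation). Connexin genes Gjb2 and Gjb6, whose products join keratinocytes, rose in the same comparison by 2.67 ± 0.39 and 1.95 ± 0.28 (log2, SE, n = 4 each). The EGFR ligand genes Hbegf, Areg and Epgn rose by 0.87 to 2.32 (log2). In week 1 icKO epidermis the glutathione transferase gene Gsta4 rose by 7.11 and Gstm1 fell by 1.77 (log2, relative to the all-gene median, n = 2 each). In week 1 icKO dermis Hmox1 and Dpt rose by 1.54 and 1.73, and the vessel genes Cdh5 and Tie1 fell by 1.27 and 1.28 on the same scale (n = 2 each).

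Across the comparisons that share no libraries, the log2 changes of week 1 epidermis and dermis had a correlation across genes of 0.35, those of day 3 epidermis and day 3 dermis of -0.093, and those of day 3 and week 1 dermis of -0.312. Genes are not independent replicates. The response to STAT3i in WT and icKO epidermis had a correlation across genes of 0.208, with 77 genes higher in both (39.1 expected by chance) and 96 lower in both (28.3 expected). These expected numbers assume independent calls, although both responses used the same spread estimate for each gene. The authors' deposited tables held 5088 entries at p < 0.05 for untreated day 3 icKO against WT and 6962 with STAT3i, and the 1679 and 4496 genes called here had the same direction there. At week 1, direction was compared only for called genes with a single entry in those tables, 4574 in epidermis and 4464 in dermis, and was the same for each.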
